A study of Mus musculus with 12 samples.

How the data were processed

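Spinal cord cells of wild-type C57BL/6 mouse embryos at embryonic day 12 were dissociated with trypsin and plated in Neurobasal medium with B27 supplement, per the labels' protocols. The wells were coated with poly-D-lysine (PDL) at 20 μg/ml. Some also received laminin at 1 μg/ml, membranes of wild-type myelin at 10 μg/ml, or both. RNA was extracted after 48 hours and made into paired-end libraries with a TruSeq RNA kit, per the labels. The 4 coats had 3 libraries each (12 in all), which the labels call biological replicates. The labels do not say whether these came from separate litters or culture days, so a p-value measures the spread between these wells. Wells with a myelin coat and no cells were also collected, per the labels, and are not analysed here.

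One table of the whole series was used. It held whole-number counts per gene for the 12 libraries, which the authors deposited without normalization. It also held the authors' own comparisons, deposited as log2 fold changes and as p-values adjusted for multiple testing. The authors' 12 columns of normalized values were not used, since the counts themselves were tested. The submitters' processing notes name CASAVA 1.8.2, edgeR with no version given, and the genome builds mm10 and GRCm38. The aligner, the program that counted reads, the gene annotation and the strand setting are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner may therefore share 1 count. Coordinates are those of GENCODE M21 on GRCm38, matched by gene symbol.

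The table had 21033 entries, of which 3 named no gene and 21030 named genes. A spreadsheet had turned 27 gene symbols into dates, and 25 of them were restored. An Entrez identifier was given for 17413 genes. The 3 entries without a gene were left out of library sizes and tests. They held the reads outside annotated genes (8.46% to 19.4% of all counts), the reads aligned to several places (11.5% to 13.6%) and the reads matching several genes (0.579% to 0.717%). Counts in genes ranged from 36061511 to 45024091 per library, and 17870 to 19112 genes were detected in each. Levels are given as CPM, counts scaled to a common library size. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom from 17.5 to 69.3. Each was kept as its own sample.

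The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, statmod 1.5.0 and DESeq2 1.42.0. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr on the 4 groups (15737 genes), library sizes were scaled by TMM factors, and the quasi-likelihood test of edgeR was applied with robust dispersions. All 12 libraries entered one fit with a coefficient per coat and no replicate block. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A fold change is a log2 value with its standard error (SE), and CPM values are means with the standard deviation (SD) of 3 libraries. There were 8 comparisons: the 6 pairs of coats, the myelin effect averaged over laminin (6 libraries against 6), and the interaction of myelin with laminin, which tests whether the myelin effect differed with and without laminin.

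The labels give each coat replicate numbers 1 to 3. Whether these numbers pair the libraries was checked on the deviations of log2 CPM (prior count 2) from the group means. Every one of the 18 pairs of libraries with the same number correlated above 0.1 (0.218 to 0.83), against -0.77 to 0.243 for the 36 pairs with different numbers. The first principal component held 66.8% of the variance and followed the number with an R squared of 0.993. All 12 libraries correlated best with one of their own number. The numbers were therefore taken to mark a shared preparation, which is a reading of the counts and not of the labels. The biological coefficient of variation was 0.205 without the replicate number as a block and 0.09 with it. Values from the fit with the block are printed beside a result where they change the call or move a count by over 1.5 times.

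Gene lists for cell types and pathways (34 lists) were written before the data were examined, as were the comparisons, the tests and the rule for named genes. In 33 lists at least 3 members could be tested. The list of transcripts encoded by the mitochondrial genome had no member in the table. Each list was compared with the other genes by camera with a preset correlation between genes of 0.01, two-sided, and adjusted over the lists within a comparison. The share of members past the threshold was also counted after adjustment over the list alone. With a correlation estimated from each list, 4 of the 76 list calls over all 8 comparisons remained under 0.05. They were sensory and neural crest genes with laminin plus myelin against Laminin, and those genes, astroglial genes and mature myelin genes with Myelin against Laminin. The rotation test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 1.

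Genes were named by a fixed rule. In the comparisons of Myelin with PDL, Laminin with PDL, laminin plus myelin with Laminin, and Myelin with Laminin, these were the 6 largest rises and the 6 largest falls. They were taken among genes with an adjusted p under 0.05, no overlap between the libraries of the groups and at least 5 CPM in the higher group. Predicted genes, pseudogenes and entries without a symbol were passed over. In the other 4 comparisons, 3 genes were named per direction. For each list with a camera call or at least 3 members past the threshold, the 3 members with the smallest p were named, with some left out in the comparisons reported briefly. The genes Negr1, Lsamp, Ntm, Opcml, Iglon5, Gap43, Tubb3, Sox2, Mki67, Gfap, Mbp and Mobp were always given. Some genes the rule would name are not reported here. Where fewer than 6 genes passed, all were named, and where none passed, the 3 with the smallest p. The same rule was applied to the fit with the block, a step added after the data had been seen.

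Alternatives planned at the start were DESeq2, limma-voom, relative log expression and upper-quartile scaling factors, no filter on low counts, a filter of 5 CPM in 3 libraries, a fit of the groups compared alone, the replicate block, each library left out in turn, an adjusted p under 0.1, and a change of at least 2-fold. The share of reads outside genes as a covariate, the block with DESeq2, limma-voom, that covariate or left-out libraries, and the fit without Laminin replicate 1 were added after the data had been seen. Comparisons that share control libraries were set against 20 simulated data sets with no effect. Regroupings of the libraries numbered 10 per pair of coats (4 with the block) and 100 drawn for the averaged effect.

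The tests were checked on simulated counts for Myelin against PDL, with 15737 genes and 200 of them changed by a known fold. Without the block, edgeR called 13.4% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 92.4% of those changed 4-fold, with 0 unchanged genes called. With the block, it called 67.2%, 94.0% and 100%, with 8 unchanged genes called. DESeq2 without the block called 38.8%, 79.1% and 93.9%, with 2 unchanged genes called, and limma-voom called 13.4%, 64.2% and 89.4%, with 1. Camera called the changed list and 0 others. Apart from the effects of the replicate number, counts were drawn independently for each gene. This check of camera therefore does not cover other correlation between the genes of a list.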

Results

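RNA was sequenced from spinal cord cells of wild-type mouse embryos at embryonic day 12, when the cord holds dividing progenitors and newly formed neurons. The cells had grown for 48 hours on 4 coats. One was poly-D-lysine alone (PDL), a synthetic polymer to which cells attach. The others added laminin, a basement membrane protein on which neurites grow readily, membranes of wild-type myelin, the lipid-rich sheath that oligodendrocytes wrap around axons, or both. The title of the series is about adult myelin of the central nervous system and the growth of axons, and its design text about transcripts of cells on these substrates. Each coat had 3 libraries, numbered 1 to 3 by the labels.

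Counts in genes were 39236227, 37484333 and 36061511 for PDL replicates 1, 2 and 3, and 45024091, 39630967 and 42060321 for Laminin. They were 41463721, 36104154 and 40223710 for Myelin, and 43932317, 42208360 and 37161693 for laminin plus myelin. The share of reads that fell outside annotated genes was 18.1% ± 1.13 (mean ± SD, n = 3) on PDL, 11.8% ± 2.89 on Laminin, 11.3% ± 0.927 on Myelin and 11.5% ± 0.468 on laminin plus myelin. All 3 PDL libraries (17.4% to 19.4%) lay above the 9 coated ones, and Laminin replicate 1 was the lowest at 8.46%. With 3 libraries against 3, an exact permutation test of a single value cannot give a p under 0.1. The most abundant gene took at most 0.681% of the counts of a library.

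The comparison of Myelin with PDL asks what contact with myelin did to the transcripts of these cells. Glial and myelin transcripts had the largest rises. Mobp (chromosome 9, 120149707 to 120181484, plus strand), a structural protein of central myelin, was at 18.1 ± 10.6 CPM on Myelin and 0.166 ± 0.107 CPM on PDL, a log2 change of 6.74 ± 0.57 (SE; adjusted p = 0.00169). Mbp (chromosome 18, 82475146 to 82585637, plus strand), which encodes myelin basic protein, was at 478 ± 258 against 30.5 ± 4.69 CPM, a change of 3.97 ± 0.39 (adjusted p = 0.00279). Plekhb1 (chromosome 7, 100642892 to 100662414, minus strand), a membrane protein with a pleckstrin homology domain, rose by 5.60 ± 0.52 (0.00234), from 1.18 ± 0.255 to 57.4 ± 36.5 CPM. S100b (chromosome 10, 76253853 to 76261159, plus strand), a calcium-binding protein of astrocytes, rose by 4.31 ± 0.54 (0.0156), from 0.987 ± 0.366 to 19.6 ± 10.8 CPM. The other rises named by size were Bgn, a small proteoglycan of the extracellular matrix (1.38 ± 0.31, adjusted p = 0.0477), and Qdpr, which regenerates tetrahydrobiopterin (0.73 ± 0.15, 0.0366). In each of these 6 genes, all 3 Myelin libraries were above all 3 PDL libraries. Mobp and Plekhb1 stayed under 0.05 whichever of the 6 libraries was left out, and Mbp did so without 5 of them (0.0511 without PDL replicate 2). The call of S100b was kept without 2 of the 6 (up to 0.139 without PDL replicate 2), and those of Bgn (up to 0.247) and Qdpr were lost without any 1 of them.

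**Figure D1:**
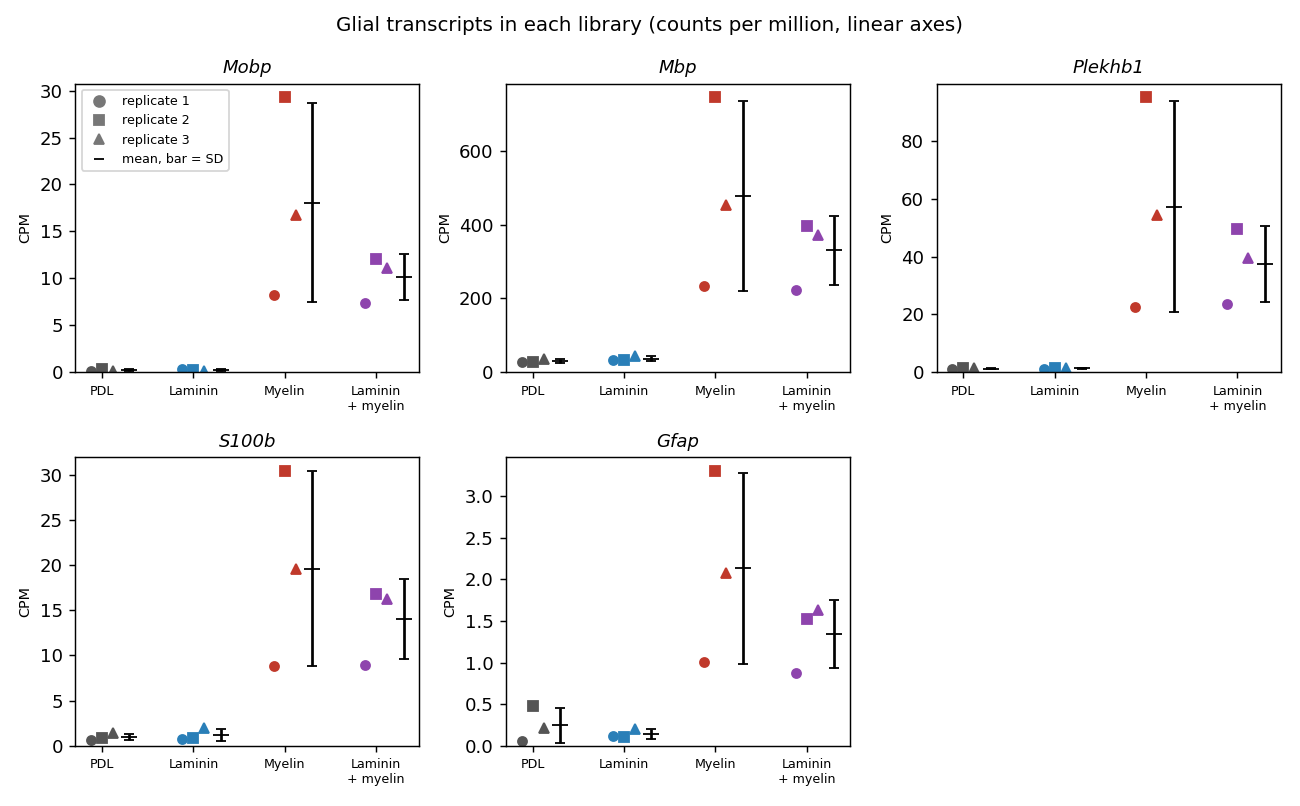
CPM of Mobp, Mbp, Plekhb1, S100b and Gfap (y axis, linear, 1 panel per gene) on the 4 coats (x axis); circles, squares and triangles are replicates 1, 2 and 3, and the black dash and bar are the mean and SD of 3 libraries. Mobp averaged 18.1 CPM on Myelin and 10.2 CPM on laminin plus myelin, against 0.166 CPM on PDL and 0.214 CPM on Laminin.

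Of the 24 genes tested on the list of mature myelin, 4 rose and 1 fell, and 19 had a log2 change above 0 (median 0.47; camera adjusted p = 4.03e-08, and adjusted p = 0.377 with an estimated correlation). The member that fell was Mog, a glycoprotein on the outer surface of myelin (-0.83), chosen after its values were seen. Adjusted over the list alone, 8 rose and 1 fell. Of 18 astroglial genes, 3 rose and 0 fell, also when adjusted over the list alone (median 0.45; adjusted p = 3.51e-05, and adjusted p = 0.377 with an estimated correlation). They were S100b, Gfap and Glul. Gfap (chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament of astrocytes, rose by 3.10 ± 0.64 (adjusted p = 0.035) to 2.13 ± 1.15 CPM, and Glul, glutamine synthetase, rose by 0.38 ± 0.08 (0.035), from 129 ± 5.93 to 168 ± 6.13 CPM. Both calls were lost without any 1 of the 6 libraries. Of 19 genes of microglia and macrophages, 1 rose, with 17 above 0 (median 0.71; adjusted p = 0.000375, and adjusted p = 0.744 with an estimated correlation). It was Trem2 (chromosome 17, 48346401 to 48354147, plus strand), a lipid receptor of microglia, which rose by 3.31 ± 0.72 (0.0408) to 1.76 ± 0.970 CPM. This call was kept without PDL replicate 3 (0.0417) and lost without any other library (up to 0.207). The complement gene C1qa had a change of 1.79 ± 0.65 (adjusted p = 0.184; 1.78 ± 0.16 and 0.000223 with the replicate number as a block). With the block, 12 microglial and 7 astroglial genes rose.

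Among the falls, Meg3 (chromosome 12, 109541001 to 109571726, plus strand), a long noncoding RNA of the nucleus, was at 1236 ± 385 CPM on Myelin and 4012 ± 1328 on PDL (-1.70 ± 0.33, adjusted p = 0.0312). The largest fall under the naming rule was that of Pram1, an adaptor protein known from myeloid cells (-1.73 ± 0.23, 0.0156; 2.65 ± 0.200 against 8.81 ± 1.44 CPM). H2-M5, a member of the class I histocompatibility family whose reads may be shared with relatives, fell by 1.60 ± 0.32 (0.0342). Spaca6, known from sperm and egg fusion, fell by 1.57 ± 0.28 (0.0282), the zinc transporter Slc39a2 by 1.52 ± 0.27 (0.0282) and the potassium channel Kcnd1 by 1.51 ± 0.30 (0.0318). Gria2 (chromosome 3, 80681450 to 80802835, minus strand), a subunit of AMPA glutamate receptors, was the 1 gene of 40 on the synapse list to fall (-1.02 ± 0.18, adjusted p = 0.0278). Its list had a camera adjusted p of 0.852. These falls came with the higher share of reads outside genes on PDL (18.1% ± 1.13 against 11.3% ± 0.927). With that share as a covariate, 0 genes passed in edgeR, and for 2 genes named here the fold shrank and the error grew: Meg3 in Myelin vs PDL went from -1.70 ± 0.33 to -0.999 with an SE of 0.675, and Gria2 to -0.59 with an SE of 0.358. Each of these 7 calls was kept without PDL replicate 3 and lost without any other of the 6 libraries (up to 0.208 for Meg3 and 0.206 for Gria2, without Myelin replicate 2).

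**Figure D2:**
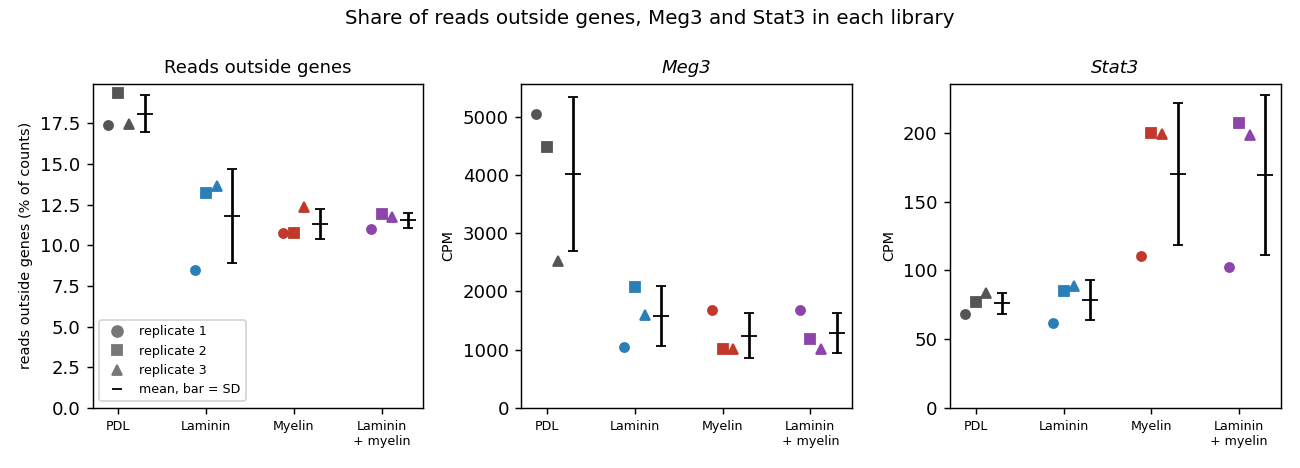
Reads outside genes as a percentage of counts, Meg3 CPM and Stat3 CPM (y axes, linear) on the 4 coats (x axis); circles, squares and triangles are replicates 1, 2 and 3, and the black dash and bar are the mean and SD of 3 libraries. The PDL libraries lie at 17.4% to 19.4% of reads outside genes, and Stat3 averages 170 CPM on Myelin and 76.2 CPM on PDL.

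Other lists moved by less. Of 32 growth-associated genes, those reported in growing or regenerating neurons, 0 passed and 27 were above 0 (median 0.18; adjusted p = 0.00462, and adjusted p = 0.377 with an estimated correlation; 0.0598 without Myelin replicate 2). Stat3 (chromosome 11, 100885098 to 100939540, minus strand), a transcription factor of cytokine signalling, was at 170 ± 51.7 against 76.2 ± 7.74 CPM (1.16 ± 0.28, adjusted p = 0.0565), and with the block it rose by 1.10 ± 0.13 (0.00183). Gap43, a growth cone protein, was at 504 ± 81.0 against 388 ± 61.7 CPM (0.38 ± 0.22, 0.408; 0.38 ± 0.09 and 0.0156 with the block), and Marcks and Marcksl1 had changes of 0.24 ± 0.09 and 0.26 ± 0.12. All 39 ribosomal protein genes were above 0 and 0 passed (median 0.26; adjusted p = 1.32e-05, and adjusted p = 0.744 with an estimated correlation), with values of 0.38 ± 0.21 for Rpl23, 0.25 ± 0.14 for Rpl30 and 0.24 ± 0.14 for Rpl8, whose reads processed pseudogenes may share. Of 28 genes of hypoxia and glycolysis, 23 were above 0 and 2 fell (1 rose and 2 fell adjusted over the list alone; median 0.24; adjusted p = 0.00725, and adjusted p = 0.377 with an estimated correlation). The falls were those of Vegfa, the vascular growth factor (-0.67 ± 0.14, 0.0397), and Pfkp, a phosphofructokinase (-1.25 ± 0.27, 0.0413), opposite in sign to the list's median. With the share of reads outside genes as a covariate both turned in sign (Vegfa 0.01 with an SE of 0.184, Pfkp 0.221 with an SE of 0.326). Each of the 2 calls was kept without 1 of the 6 libraries (up to 0.221 and 0.244 without Myelin replicate 2). Egln1 was at 0.22 ± 0.06 (0.0951).

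The list of cholesterol synthesis had an adjusted p of 0.00725 (21 of 25 above 0, median 0.18; adjusted p = 0.744 with an estimated correlation), with Fdps at 0.30 ± 0.11, Acat2 at 0.22 ± 0.09 and Tm7sf2 at -0.42 ± 0.13, and 0 members passed. It was not called without PDL replicate 3 (0.0551) or Myelin replicate 2 (0.124). Targets of YAP and serum response factor, which respond to tension, had 20 of 26 members above 0 (median 0.18; adjusted p = 0.00665, and adjusted p = 0.377 with an estimated correlation). The smooth muscle actin Acta2 was at 1.07 ± 0.30 (0.0881; with the block 1.06 ± 0.22 and 0.0108), Ctgf at 0.71 ± 0.22 (0.12; 0.0171 with the block) and Amotl1 at -0.21 ± 0.07. Of 37 genes of the neuronal cytoskeleton and its transport, 29 were above 0 (median 0.11; adjusted p = 0.00725, and adjusted p = 0.744 with an estimated correlation), with Tuba1b at 0.29 ± 0.09, Tubb5 at 0.23 ± 0.08 and Rac1 at 0.23 ± 0.08. That call was lost without PDL replicate 3 (0.114), Myelin replicate 1 (0.0649) or Myelin replicate 2 (0.0609), and for cytoskeleton_transport in Myelin vs PDL the direction turned with the share of reads outside genes as a covariate (0.358). With the block, 7 more lists passed: neural progenitors (0.017), pan-neuronal genes (0.0119), sensory and neural crest genes (0.00311), the IgLON family (0.032), sterol and lipid loading (0.0119), immediate early genes (0.000574) and ERK feedback (0.0206). With an estimated correlation as well, their adjusted p were 0.63, 0.266, 0.229, 0.229, 0.266, 0.229 and 0.534.

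The remaining lists were not called in Myelin against PDL with or without the block: axon guidance (0.225), spinal neuron classes (0.571), oligodendrocyte precursors (0.17), endothelial and mural genes (0.0727), mesenchymal genes (0.0963), erythroid genes (0.764), epithelial and ependymal genes (0.588), neural adhesion (0.318), receptors of myelin inhibitors (0.36), integrins and laminin receptors (0.315), basement membrane (0.106), cell cycle (0.852), the integrated stress response (0.0727), p53 and apoptosis (0.256), interferon and inflammation (0.366), and Notch, Wnt and BMP targets (0.173).

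Negr1 (chromosome 3, 156561794 to 157316445, plus strand), an IgLON adhesion molecule named for neuronal growth, was at 160 ± 7.04 CPM on Myelin and 129 ± 6.78 on PDL (0.31 ± 0.08, adjusted p = 0.0603). With the block it rose (0.31 ± 0.06, 0.0105). The other IgLON genes had changes of 0.19 ± 0.21 (Lsamp), 0.19 ± 0.14 (Ntm), 0.12 ± 0.18 (Opcml) and 0.07 ± 0.26 (Iglon5), with adjusted p from 0.527 to 0.933. Tubb3, the neuronal tubulin, was at 0.18 ± 0.14 (0.556). The progenitor factor Sox2 was at 0.34 ± 0.33 (0.648; with the block 0.31 ± 0.09 and 0.0385), and the proliferation marker Mki67 at -0.25 ± 0.33 (0.757).

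In all, 360 of 15737 genes passed in Myelin against PDL, 23 higher and 337 lower, and 121 of them by at least 2-fold. The count was 3 and 2 without PDL replicates 1 and 2, and 4, 3 and 3 without Myelin replicates 1, 2 and 3. With the block, 2268 genes passed, 687 higher and 1581 lower, and 682, 286, 1328, 160 and 751 did without those same libraries. DESeq2 called 1089. In the authors' deposited table, 452 genes had an adjusted p under 0.05 for this pair, 43 higher and 409 lower on Myelin, with log2 changes of 6.74 for Mobp, 3.97 for Mbp and 3.11 for Gfap.

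Laminin against PDL sets a reference, the response to a substrate known to favour neurite growth. No gene of the YAP and serum response factor list passed. Tpm2, a tropomyosin of muscle, was at 1.03 ± 0.23 (adjusted p = 0.117), Acta2 (chromosome 19, 34241090 to 34255590, minus strand) at 1.29 ± 0.30 (0.125), with 44.6 ± 8.14 CPM on Laminin and 18.2 ± 6.01 on PDL, and Actg2, the enteric smooth muscle actin, at 1.64 ± 0.43 (0.15). Reads of these actins may be shared with other actin genes. That list had 21 of 26 members above 0 (median 0.18; adjusted p = 0.000355, and adjusted p = 0.753 with an estimated correlation). Over all genes 0 of its members passed, and 4 rose adjusted over the list alone. All 39 ribosomal protein genes were above 0 (median 0.34; adjusted p = 1.25e-09, and adjusted p = 0.975 with an estimated correlation), with Rpl30 at 0.37 ± 0.14, Rpl8 at 0.35 ± 0.14 and Rpl15 at 0.33 ± 0.13. Cholesterol synthesis was the third list called (20 of 25 above 0, median 0.16; adjusted p = 0.0211, and adjusted p = 0.975 with an estimated correlation), with Fdps at 0.34 ± 0.11, Acat2 at 0.26 ± 0.09 and Ebp at 0.23 ± 0.10. Its call was lost without PDL replicate 1 (0.0646), PDL replicate 3 (0.11) or Laminin replicate 2 (0.597).

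No single gene passed in Laminin against PDL. The smallest p, each with an adjusted p of 0.116, were those of Cspp1, a centrosome protein (28.1 ± 3.53 against 49.4 ± 3.61 CPM, -0.81 ± 0.11), and the zinc finger genes Zfp182 (-0.63 ± 0.10) and Zfp932 (-0.48 ± 0.08). Glial genes had changes of 0.36 ± 0.69 (Mobp, 0.854), 0.23 ± 0.35 (Mbp, 0.807) and -0.77 ± 0.71 (Gfap, 0.629). Negr1 was at 0.16 ± 0.08 (0.306), Ntm at 0.21 ± 0.14, Lsamp at 0.17 ± 0.21, Opcml at 0.03 ± 0.18 and Iglon5 at 0.10 ± 0.26 (0.465 to 0.959). Gap43 was at 0.33 ± 0.22 (0.45), Tubb3 at 0.25 ± 0.14 (0.39), Sox2 at 0.07 ± 0.33 (0.946) and Mki67 at -0.64 ± 0.33 (0.348).

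Where edgeR without the block called 0 genes in Laminin against PDL, 2735 had an unadjusted p under 0.05, DESeq2 called 556 and limma-voom called 0. With the block, 1282 genes passed, 419 higher and 863 lower. That count fell to 0 without PDL replicate 1 or PDL replicate 2 and to 641 without Laminin replicate 1, and it was 2481 without Laminin replicate 2. The rises named by size were Acta2 (1.31 ± 0.22, adjusted p = 0.0171), Col8a1, a short-chain collagen (1.15 ± 0.20), Tgfb3, a growth factor of the TGF-beta family (1.08 ± 0.19), Bgn (0.93 ± 0.20), the galectin Lgals1 (0.90 ± 0.20) and Tagln, a smooth muscle protein (0.88 ± 0.21, 0.0338). The falls were those of Sycp1, a meiotic protein (-1.53 ± 0.19, 0.0171), H2-M5 (-1.36 ± 0.29), Spaca6 (-1.31 ± 0.26), Ubap1l (-1.28 ± 0.27), Meg3 (-1.27 ± 0.26, 0.0239) and Srrm4os (-1.25 ± 0.19), an antisense transcript whose reads may include those of Srrm4. With the block Mki67 fell (-0.64 ± 0.13, 0.0225), Gap43 rose (0.31 ± 0.09, 0.0477), and the lists of microglia (0.00188) and growth-associated genes (0.00996) were called, both with an adjusted p of 0.751 with an estimated correlation. The share of reads outside genes was also lower on Laminin (11.8% ± 2.89 against 18.1% ± 1.13), and with the block and that share as a covariate 0 genes passed. The authors' deposited table has 76 genes with an adjusted p under 0.05 for this pair, 1 higher and 75 lower on Laminin.

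Adding myelin where laminin was already present asks whether the myelin effect appears on a growth-promoting substrate. Mobp rose by 5.55 ± 0.54 (adjusted p = 0.00704), from 0.214 ± 0.0818 CPM on Laminin to 10.2 ± 2.44 on laminin plus myelin. Plekhb1 rose by 4.82 ± 0.50 (0.00744), from 1.33 ± 0.151 to 37.5 ± 13.2 CPM, and Mbp by 3.21 ± 0.38 (0.0168), from 35.8 ± 7.04 to 331 ± 94.6 CPM. These were the 3 genes past the threshold, and 0 fell. S100b was at 14.0 ± 4.41 against 1.21 ± 0.690 CPM (3.53 ± 0.52, 0.096; with the block 3.54 ± 0.28 and 9.64e-05). The count was 0 without Laminin replicate 1, 2 or 3. Without Laminin replicate 1 the adjusted p of Mobp was 0.119, that of Plekhb1 0.216 and that of Mbp 0.355. With the block, 15 genes rose and 1 fell. The count with the block was 186 without Laminin replicate 1, 10 without Laminin replicate 2, Laminin replicate 3 or replicate 2 of laminin plus myelin, and 6 without replicate 3 of laminin plus myelin. Beyond those 4 genes the rises with the block included Gfap (3.21 ± 0.40), Prph, an intermediate filament of peripheral neurons (3.02 ± 0.16, 1.68e-06), Trem2 (2.23 ± 0.23), the lipid carrier Apoe (1.16 ± 0.16, 0.0136) and Stat3 (1.07 ± 0.13, 0.00443), which was at 169 ± 58.4 against 78.7 ± 14.7 CPM. The single fall was that of Il1b, an inflammatory cytokine (-2.44, 0.0136), chosen after its values were seen. DESeq2 called 6 genes and limma-voom 1, and 201 had an unadjusted p under 0.05 in edgeR.

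In this comparison, 15 lists were called, and 3 of these calls held whichever library was left out: mature myelin (3 of 24 rose, 5 adjusted over the list alone; adjusted p = 6.11e-24, and adjusted p = 0.0947 with an estimated correlation), astroglia (0 passed, 3 adjusted over the list alone; 3.25e-14, and adjusted p = 0.0806 with an estimated correlation), and sensory and neural crest genes (0 passed; 6.26e-05, and 0.0445 with an estimated correlation). The last list included Prph (2.99 ± 0.67), and without Laminin replicate 1, with the block, its median was 0.03 and its adjusted p = 0.115 with an estimated correlation. Microglia were called with Trem2 at 2.27 ± 0.66 and Mrc1 at 2.21 ± 1.05 (0.00021, and adjusted p = 0.729 with an estimated correlation). Of 36 cell cycle genes, 31 were above 0 and 0 passed (0.00139, and adjusted p = 0.729 with an estimated correlation; Tpx2 at 0.36, Mki67 at 0.45 ± 0.33, Top2a at 0.37). The other lists higher with myelin were neural progenitors (0.0187; Notch1 at 0.42 ± 0.32, Dbx1 at -1.09 ± 0.41), axon guidance (0.000817; Plxnd1 at 0.61), basement membrane (0.0162; Lamc1 at 0.36), sterol and lipid loading (0.00584; Apoe at 1.17 ± 0.48), immediate early genes (0.0031; Egr3 at 1.00 ± 0.40), ERK feedback (0.00584; Spry4 at 0.36), Notch, Wnt and BMP targets (0.0433; Id3 at 0.33), the cytoskeleton (0.0339; Map1a at 0.20) and cholesterol synthesis (0.05, just under the threshold before rounding; Hsd17b7 at 0.17). Ribosomal proteins were lower (0.0019, and adjusted p = 0.729 with an estimated correlation; Rps14 at -0.37), and this direction turned without Laminin replicate 1 (with the block a median of 0.13 and 2.98e-10, and adjusted p = 0.115 with an estimated correlation). With an estimated correlation, the adjusted p was 0.632 for ERK feedback and 0.729 for the other lists from neural progenitors to cholesterol synthesis. Without replicate 3 of laminin plus myelin the direction turned for cell cycle (0.28), neural progenitors (0.204) and basement membrane (0.779). It turned for basement membrane without Laminin replicate 1 (0.648), cholesterol synthesis without Laminin replicate 3 (0.885) and ribosomal proteins without replicate 1 of laminin plus myelin (0.523). Leaving out Laminin replicate 1 ended 10 of the 15 calls (0.118 to 0.962), replicate 3 of laminin plus myelin 8 (0.204 to 0.983), replicate 1 of laminin plus myelin 4 (0.125 to 0.972), Laminin replicate 2 ended 3 (0.333 to 0.452), Laminin replicate 3 ended 2 (0.885), and replicate 2 of laminin plus myelin 1 (0.205). These tallies are without the block. With the block and without Laminin replicate 1, microglia (2.42e-10), immediate early genes (5.83e-05) and neural progenitors (0.000187) stayed called, higher with myelin. So did sterol and lipid loading (0.00514), Notch, Wnt and BMP targets (0.00557) and ERK feedback (0.0389). With an estimated correlation these lists were at 0.16 to 0.724. In that fit both remaining Laminin libraries had a higher share of reads outside genes than any with myelin. These calls can therefore not be told apart from that share. Axon guidance (0.779), basement membrane (0.267) and cholesterol synthesis (0.0539) were not called. With the block and all libraries, hypoxia and glycolysis was also called (0.0119, and adjusted p = 0.558 with an estimated correlation), and cholesterol synthesis (0.1) and the cytoskeleton (0.105) were not. The IgLON genes ranged from -0.06 (Ntm) to 0.19 ± 0.08 (Negr1), with Lsamp and Iglon5 at -0.01 and Opcml at 0.12. Gap43 was at 0.03 ± 0.22, Tubb3 at -0.09 ± 0.14 and Sox2 at 0.31 ± 0.33, each with an adjusted p of 1.

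Myelin and Laminin were also compared directly, which asks how the transcripts differ between the coats. Glial genes were again higher on Myelin: Mobp by 6.38 ± 0.55 (adjusted p = 0.00203), Plekhb1 by 5.43 ± 0.52 (0.00271), S100b by 4.01 ± 0.52 (0.0332) and Mbp by 3.74 ± 0.39 (0.00455). These 4 genes were all that passed, none of them with overlapping libraries, and 0 were lower. A fit of Myelin and Laminin alone called 0 genes in edgeR. Gfap was at 3.88 ± 0.67 (0.348; with the block 3.80 ± 0.39 and 0.00109). Astroglia (4.66e-17), mature myelin (9.94e-33) and sensory and neural crest genes (2.62e-05) were called with every library left out in turn, and with an estimated correlation their adjusted p were 0.0421, 0.0421 and 0.0378. Without Laminin replicate 1, in the fit with the block, the values with an estimated correlation were 0.102, 0.0943 and 0.0943. Of the sensory list, Prph was at 2.82 ± 0.67 (with the block 2.83 ± 0.16 and 2.4e-06), and Clu of the astroglial list was at 0.72. Microglia (2.03e-06; Trem2 at 2.26 ± 0.66, Mrc1 at 2.22) were called, and adjusted p = 0.738 with an estimated correlation.

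A further 10 lists were called between Myelin and Laminin: neural progenitors (0.0053; Sox1 at 0.39), axon guidance (0.000438; Nrp1 at 0.17), neural adhesion (0.0412; Cntn2 at 0.21), basement membrane (0.00877; Thbs2 at 0.69, Fbln5 at -1.08), cell cycle (0.0128; Mki67 at 0.39), sterol and lipid loading (0.00129; Apoe at 1.24 ± 0.48), immediate early genes (0.000438; Fos at 0.74), ERK feedback (0.000457; Etv4 at 0.33), the cytoskeleton (0.00877; Enah at 0.17) and, lower on Myelin, ribosomal proteins (0.0421; Rps27 at -0.35), a direction that turned without Laminin replicate 1 (with the block a median of 0.16 and 4.81e-14, and adjusted p = 0.0943 with an estimated correlation). None of these 10 was under 0.05 with an estimated correlation (adjusted p = 0.289 for ERK feedback, 0.722 for axon guidance and sterol loading, 0.738 for immediate early genes, 0.796 for progenitors, basement membrane and the cytoskeleton, 0.81 for adhesion and cell cycle, and 0.825 for ribosomal proteins). The direction turned without Laminin replicate 1 for basement membrane (0.776), without Myelin replicate 1 for neural adhesion (0.653) and ribosomal proteins (0.108), and without Myelin replicate 3 for neural progenitors (0.88) and cell cycle (0.0865). Leaving out Laminin replicate 1 ended 10 list calls (0.0588 to 0.776), Myelin replicate 3 ended 6 (0.0865 to 0.88), Myelin replicate 1 ended 4 (0.108 to 0.653), Laminin replicate 3 ended 3 (0.177 to 0.566), Laminin replicate 2 ended 2 (0.2 to 0.776) and Myelin replicate 2 ended 2 (0.158 to 0.232). These tallies are without the block. With the block and without Laminin replicate 1, microglia (1.79e-17), cell cycle (7.43e-08) and immediate early genes (5.83e-07) stayed called, higher on Myelin. So did neural progenitors (0.000128), sterol and lipid loading (0.00302) and ERK feedback (0.0116). With an estimated correlation these lists were at 0.0943 to 0.611. Both Laminin libraries left in that fit had a higher share of reads outside genes than any on Myelin, so these calls cannot be told apart from it. Axon guidance (0.798), basement membrane (0.292) and neural adhesion (0.391) were not called. With the block and all libraries, hypoxia and glycolysis was called (0.00375, and adjusted p = 0.541 with an estimated correlation) and neural adhesion was not (0.0615). Negr1 was at 0.15 ± 0.08, Lsamp at 0.02, Ntm at -0.02, Opcml at 0.09, Iglon5 at -0.03, Gap43 at 0.05, Tubb3 at -0.07 and Sox2 at 0.27, each with an adjusted p of 1. The 4 genes became 1 and 2 without Laminin replicates 1 and 2. With the block, 17 genes were higher and 1 lower, including Stat3 (1.08, 0.00335), C1qa (0.94, 0.034) and, as the 1 lower gene and chosen after its values were seen, Il1b (-2.62, 0.00926). That total of 18 was 336 without Laminin replicate 1, 11 without Laminin replicate 3 and 9 without Myelin replicate 3. DESeq2 called 9 genes and limma-voom 1.

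**Figure D3:**
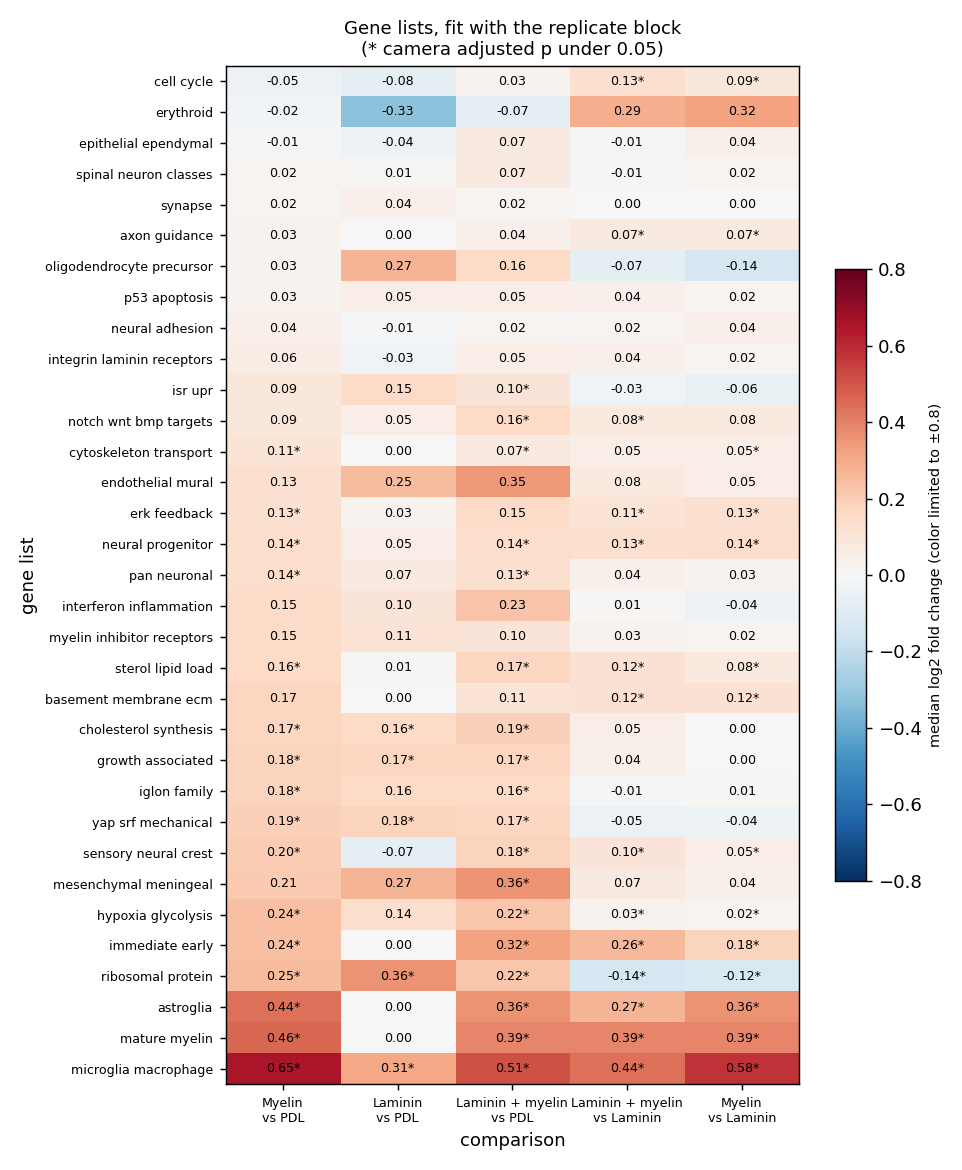
Median log2 fold change of the 33 gene lists (rows) in 5 comparisons (columns) from the fit with the replicate block; the colour scale stops at -0.8 and 0.8, and a star marks a camera adjusted p under 0.05. In Myelin against PDL the medians were 0.65 for microglia, 0.46 for mature myelin and 0.44 for astroglia, and ribosomal proteins had a median of 0.36 in Laminin against PDL.

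Both coats together were compared with PDL for their joint effect. The largest rises were those of Mobp (5.91 ± 0.56, adjusted p = 0.00561), Plekhb1 (4.99 ± 0.51, 0.00627), S100b (3.82 ± 0.53, 0.0285) and Mbp (3.44 ± 0.38, 0.00946). Falls included Ubap1l (-1.81 ± 0.38, 0.0488), Meg3 (-1.64 ± 0.33, 0.0456; 1290 ± 342 CPM) and Srrm4os (-1.56 ± 0.21, 0.0285). Negr1 was at 165 ± 14.4 against 129 ± 6.78 CPM (0.36 ± 0.08, 0.0503; 0.00803 with the block). Gfap was at 2.44 ± 0.63 (0.0805; 0.00542 with the block), Gap43 at 0.36 (0.442; 0.0211 with the block), Sox2 at 0.38, Tubb3 at 0.16, Mki67 at -0.19, Lsamp at 0.16, Ntm at 0.15, Opcml at 0.15 and Iglon5 at 0.09. In total 8 genes were higher and 188 lower, next to a share of reads outside genes of 18.1% ± 1.13 on PDL and 11.5% ± 0.468 on laminin plus myelin. With that share as a covariate 0 genes passed, with or without the block, and DESeq2 called 985 (159 higher, 826 lower). The count of 196 was 0 and 1 without PDL replicates 1 and 2, and 5, 2 and 3 without replicates 1, 2 and 3 of laminin plus myelin. With the block it was 2133 (676 higher), and 429, 14, 1253, 261 and 352 without those libraries. The 10 lists called were astroglia (0.000275), mature myelin (1.37e-05), microglia (0.00231), mesenchymal genes (0.0235), growth-associated genes (0.00408), cholesterol synthesis (0.000275), hypoxia and glycolysis (0.00961), YAP and serum response factor targets (0.00231), the cytoskeleton (0.0162) and ribosomal proteins (0.000108). With an estimated correlation their adjusted p ran from 0.398 to 0.795, and with the covariate cytoskeleton_transport in Laminin_Myelin vs PDL turned in direction (0.294). Calls were lost for microglia without PDL replicate 1 (0.108) or replicate 3 of laminin plus myelin (0.146), mesenchymal genes without PDL replicate 2 (0.0864), hypoxia without replicate 3 of laminin plus myelin (0.119), the cytoskeleton without PDL replicate 3 (0.176) or replicate 1 of laminin plus myelin (0.189), and ribosomal proteins without PDL replicate 1 (0.0681). With the block, 8 more lists were called: neural progenitors (0.0239), pan-neuronal genes (0.0141), sensory and neural crest genes (0.00329), the IgLON family (0.0239), sterol and lipid loading (0.0199), immediate early genes (0.00483), the integrated stress response (0.0408) and Notch, Wnt and BMP targets (0.0294). With an estimated correlation these were at 0.265 to 0.769.

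No gene passed when laminin was added to myelin: edgeR called 0 in laminin plus myelin against Myelin with or without the block, 29 genes had an unadjusted p under 0.05 (155 with the block), and DESeq2 and limma-voom called 0. The smallest p were those of Cep89 (0.30 ± 0.09), Mobp (-0.83 ± 0.40) and Enoph1 (0.19 ± 0.09), each with an adjusted p of 1. Mature myelin genes were lower as a list (5.95e-05, and adjusted p = 0.976 with an estimated correlation), with Mbp at -0.53 and Tspan2 at -0.25, and cholesterol synthesis was higher (0.0381, and adjusted p = 0.976 with an estimated correlation), with Mvd at 0.14. The first call was lost without Myelin replicate 2 (0.922), Myelin replicate 3 (0.295) or replicate 1 of laminin plus myelin (0.717). The second was lost without Myelin replicate 1 (0.359), Myelin replicate 3 (0.632, with its direction turned), or replicate 1 (0.76) or 2 (0.484) of laminin plus myelin. With the block, astroglia (0.0203, and adjusted p = 0.997 with an estimated correlation) and microglia (4.02e-06, 0.737) were also lower and mesenchymal genes higher (0.035, 0.737). Gfap was at -0.66 and Negr1 at 0.04.

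Averaged over laminin, the 6 libraries with myelin had higher Mobp (6.15 ± 0.39, adjusted p = 8.31e-05), Plekhb1 (5.21 ± 0.36, 0.000106), Mbp (3.59 ± 0.27, 0.000177; 404 ± 192 against 33.2 ± 6.09 CPM, n = 6) and S100b (3.92 ± 0.37, 0.00137). These 4 calls held whichever of the 12 libraries was left out, and they were all that passed in edgeR. The count was 673 without Laminin replicate 1, 7 without Myelin replicate 1 and 22 without replicate 1 of laminin plus myelin. DESeq2 called 611 genes and limma-voom 1, and no gene passed in edgeR with the share of reads outside genes as a covariate. Gfap (3.16 ± 0.46, 0.0624), Trem2 (2.79, 0.0785), Prph (2.80, 0.0785), Stat3 (1.13 ± 0.20, 0.0785) and Negr1 (0.25 ± 0.06, 0.0909) did not pass without the block. With the block, Gfap (9.29e-05), Negr1 (0.0119), Sox2 (0.30, 0.0187) and Gap43 (0.0495) passed, as did 11 of the 19 microglial genes. In that fit 1358 genes passed, 477 higher and 881 lower, and 47 of the lower ones fell by at least 2-fold. The naming rule asks for no overlap between libraries and for at least 5 CPM. The largest falls it allowed were those of Tatdn3 (-0.54, 0.0136), Setd4 (-0.53) and Metap1d (-0.45). The count of 1358 ranged from 96 without PDL replicate 2 to 4795 without Laminin replicate 1. It was 556 without PDL replicate 1, 421 and 232 without Laminin replicates 2 and 3, 157 and 468 without Myelin replicates 2 and 3, and 301 and 410 without replicates 2 and 3 of laminin plus myelin. Values for Tubb3 (0.05), Mki67 (0.10), Lsamp (0.09), Ntm (0.07), Opcml (0.12) and Iglon5 (0.03) did not pass. Of 21 lists called, 7 held without each library: mature myelin (1.08e-18, and adjusted p = 0.183 with an estimated correlation), astroglia (3.37e-11, 0.163), microglia (4.72e-06, 0.603), sensory and neural crest genes (0.00213, 0.157), growth-associated genes (0.00341, 0.241), cholesterol synthesis (0.00294, 0.63) and the cytoskeleton (0.00289, 0.603), with the p at an estimated correlation second in each pair. With the share of reads outside genes as a covariate, cytoskeleton_transport in Myelin averaged over laminin turned in direction (0.709), as did pan_neuronal in Myelin averaged over laminin (0.0593) and iglon_family in Myelin averaged over laminin (0.393). Of the other 14, with adjusted p from 0.00404 (hypoxia and glycolysis) to 0.0467 and from 0.25 to 0.748 with an estimated correlation, 12 ended without Laminin replicate 1 (0.0666 to 0.431), 9 without replicate 3 of laminin plus myelin, and 7 without Myelin replicate 3. Without PDL replicates 1, 2 and 3, 3, 3 and 5 ended, without Laminin replicates 2 and 3, 3 and 2, without Myelin replicates 1 and 2, 5 and 3, and without replicates 1 and 2 of laminin plus myelin, 4 and 2. These tallies are without the block. With the block and without Laminin replicate 1, hypoxia and glycolysis (0.000354), immediate early genes (0.000354) and neural progenitors (0.00255) stayed called, higher with myelin. So did sterol and lipid loading (0.00532), Notch, Wnt and BMP targets (0.0247) and ERK feedback (0.0263). With an estimated correlation these lists were at 0.207 to 0.607. Every library without myelin in that fit had a higher share of reads outside genes than every library with it. These calls can therefore not be told apart from that share. The others of the 12 were not called in that fit (0.123 to 0.597). With the block and all libraries, endothelial and mural genes (0.0857), mesenchymal genes (0.0651), YAP and serum response factor targets (0.0727) and ribosomal proteins (0.0651) were not called.

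Whether the myelin effect differed with laminin was tested by the interaction, in which no gene passed: edgeR called 0, 1042 genes had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. The smallest adjusted p was 0.705, shared by Zfp182 (0.76 ± 0.13), Cspp1 (0.84 ± 0.15) and Glt8d1 (0.49 ± 0.10), and 0.167 with the block, which also called 0 (2603 unadjusted). Without Laminin replicate 1, edgeR with the block called 83, and DESeq2 with the block and all libraries called 241, 220 of them higher. Mobp was at -1.19 ± 0.80 (0.77), Mbp at -0.76 (0.767), Negr1 at -0.12 (0.845), Gap43 at -0.35 (0.831), Mki67 at 0.70 (0.769), Tubb3 at -0.27, Sox2 at -0.03 and Gfap at 0.11. Genes that passed in only one of the myelin comparisons are therefore not shown to differ between them. Of the lists, ribosomal proteins had 0 of 39 members above 0 (median -0.36; adjusted p = 5.3e-10, and adjusted p = 0.964 with an estimated correlation; Rpl8 at -0.38, Rps14 at -0.58, Rpl15 at -0.33). YAP and serum response factor targets were also negative (0.00235, and adjusted p = 0.964 with an estimated correlation; Acta2 at -1.28 ± 0.42, Tpm2 at -0.87, Myl9 at -0.83), and both calls held without each library. The size for ribosomal proteins depended on 1 library: with the block the median was -0.39, and without Laminin replicate 1 it was -0.12 (7.55e-07, and adjusted p = 0.436 with an estimated correlation). With the block, microglia (1.49e-06, and adjusted p = 0.894 with an estimated correlation) and growth-associated genes (0.0125, and adjusted p = 0.894 with an estimated correlation) were negative too. PDL, which enters the interaction, had 18.1% of reads outside genes, against 11.3% to 11.8% on the other coats. These calls can therefore not be told apart from that share. With it as a covariate and no block, camera called 21 lists in the interaction.

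Comparisons that share a control also share its chance values. With the block, Myelin against PDL and Laminin against PDL had changes that correlated across genes at 0.771 (0.485 in simulated data without effects), with a covariance of 0.1176 (0.0243 simulated, a difference of 0.0933) and the same sign in 83% of genes (65.5% simulated). They shared 137 higher and 745 lower genes, against 18.3 and 86.7 for independent lists and 0.05 and 0.05 in the simulations. For Myelin against PDL and laminin plus myelin against PDL, the correlation was 0.896 (0.489), the covariance 0.1621 (0.0246, a difference of 0.1375) and the share of the same sign 90.2% (65.8%). They shared 490 higher and 1255 lower genes, against 29.5 and 146 for independent lists. Without the block this pair shared 8 higher and 175 lower genes, against 0.0117 and 4.03. For laminin plus myelin and Myelin, each against Laminin, the correlation was 0.742 (0.488), the covariance 0.0541 (0.0245, a difference of 0.0296) and the same sign held in 83.4% (65.5%), with 13 higher genes shared against 0.0162. With 3 control libraries these could not be divided into sets of at least 2, so part of the excess may come from the shared controls, and genes are not independent replicates.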

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

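The tests of the 3 patterns weighed here were chosen only after the results were seen, and the list tests of the interaction were planned. Camera on the interaction itself called the effect of myelin different with and without laminin for 2 lists. They were targets of YAP and serum response factor (adjusted p = 0.00235) and ribosomal proteins (5.3e-10), but both had an adjusted p = 0.964 with an estimated correlation. With the replicate block these lists (0.0027 and 2.34e-09), microglia (1.49e-06) and growth-associated genes (0.0125) were called. Each had an adjusted p = 0.894 with an estimated correlation. All 4 lists had a lower change with myelin where laminin was present. The median of the ribosomal proteins went from -0.39 with the block to -0.12 without Laminin replicate 1. PDL enters the interaction with its higher share of reads outside genes, so a difference with laminin cannot be told apart from that share.

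Mobp, Plekhb1, S100b, Mbp and Gfap were higher in all 6 wells with a myelin coat, and the coat may have carried their RNA into the wells. The log2 ratio between the excesses of any 2 of these genes had a median SD of 0.155 over the wells (0.0489 to 0.252 over 10 pairs), while the excess of a gene itself had a median SD of 0.711, so the genes kept nearly 1 ratio as their amounts varied. The other 21 genes of mature myelin had a median log2 change of 0.3 (SD 1.05, 8 higher and 1 lower, with the block). This was far under the smallest change of the 5 genes (3.16). Since the 5 genes were picked for their large rises, lower changes in the remaining genes were likely whatever the source. Oligodendrocytes present or maturing in the wells are therefore not excluded. A response of the cells that raises these genes in a fixed ratio stays open. The wells with a myelin coat and no cells would test it and are not analysed here.

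Microglial genes were higher in wells with myelin, 11 of 19 past the threshold with the block. The changes ran from 2.78 ± 0.18 (Trem2) to -0.35 ± 0.12 (Itgam). Of their variation, 95.5% lay beyond their standard errors (I squared, around a pooled change of 0.51). More microglia would raise all members alike only if all reads of these genes came from microglia. That was not tested, so the spread argues against more microglia as the only change under this condition alone. Microglial RNA in the coat would make the excess follow that of Mobp from well to well, but Trem2, Mrc1 and C1qa, whose log2 changes were above 1, had SDs around Mobp of 0.74, 0.84 and 0.87, close to the SD of Mobp itself over the wells (0.739). Over all 9 members that passed and had an excess in every well, the spread around Mobp was a median 3.0 times the spread around the same culture without myelin (lowest 2.05, with P2ry12 not among them at an adjusted p of 0.077), but for the other members the excess was close to the level without myelin or smaller, which inflates its log spread. The spread of Trem2, Mrc1 and C1qa was not corrected for counting noise, and 2 of them were under 1 CPM without myelin. The coat can therefore be neither excluded nor shown as a source for any member. A change of state in microglia already present also stays open.

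PDL libraries had more reads outside genes (18.1% ± 1.13) and higher Meg3 than coated wells. The 362 chemoreceptor genes, picked by name and not tested for silence, held 8.59 CPM in sum in coated wells and 13.2 CPM on PDL. Their gain was 0.275 of the reads that DNA spread evenly would give (0.154 to 0.436). The table held no gene without a read, so receptor genes without reads are missing from this value. Reads aligned to several places were not counted in genes, and the loss of such reads in these genes was not measured. Genomic DNA is therefore not excluded as a source of part of the excess. A larger share of unspliced RNA may account for part of it. The 173 small RNA genes in introns of expressed hosts (at least 5 CPM) held 22.4 CPM in sum on PDL and 10.6 CPM in coated wells. The 29 in hosts under 5 CPM, called silent here, held 1.28 and 0.568 CPM. The mean gain per gene on PDL was a small fraction of 1 CPM. It was larger in expressed than in silent hosts by 43.6 reads (14.8 to 77.5), scaled to a common depth many times that of any library here. The log2 gains of both were nevertheless alike (1.08 and 1.17, a difference of -0.09 with bounds of -0.42 and 0.25). Across genes, the slope on the share of reads outside genes among the 9 coated libraries correlated at -0.65 with the change of Myelin against PDL. The value was -0.696 without Laminin replicate 1, and 3 of 216 orders of the share were as low (one-sided permutation p = 0.0139). The Myelin libraries enter both the slope and the change, and reordering the share does not remove this. The correlation therefore cannot decide whether there was a response to the coats with no link to the share. With the share as a covariate, Gria2 in Myelin against PDL went from -1.02 ± 0.18 to -0.59 with an SE of 0.358, so its fold shrank and its error grew, while Mobp kept its fold (6.74 ± 0.57, then 6.49 with an SE of 1.32) and lost its call to the error alone, since the share follows the coat; whether the cells or the extraction set the share stays open.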

How the results depend on the processing

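The share of reads outside genes as a covariate and the alternatives that combine the block with another setting, a left-out library included, were chosen after seeing the data. The others were planned. The pseudocount alternative applies to normalized values and was not run, since the table holds counts. The cause of the differences was not tested, except that thresholds, filters and left-out libraries change the genes or samples by construction. Of 557 gene values, RLE and upper-quartile factors left 554 and 551 with the same direction and side of the threshold, no filter 550 and limma-voom 543. Of 264 list tests they left 259, 254, 231 and 248. Libraries held 36061511 to 45024091 counts in genes, and genes too low for the filter at these depths were not tested.

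Counts with an adjusted p under 0.1 were 853 (Myelin against PDL), 677 (laminin plus myelin against PDL) and 183 (averaged), and with at least a 2-fold change 121 and 61 for the first 2. For laminin plus myelin against PDL, no filter gave 127 genes and a filter at 5 CPM 328. DESeq2 called 1089 (Myelin against PDL), 556 (Laminin against PDL), 6 (laminin plus myelin against Laminin), 9 (Myelin against Laminin), 985 (laminin plus myelin against PDL), 611 (averaged) and 9 (interaction). In limma-voom, laminin plus myelin against Laminin, Myelin against Laminin and the averaged effect had 1 gene each. Myelin against Laminin fitted on those groups alone gave 0 in edgeR.

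The replicate block gave 2268 (Myelin against PDL), 1282 (Laminin against PDL), 16 (laminin plus myelin against Laminin), 18 (Myelin against Laminin), 2133 (laminin plus myelin against PDL) and 1358 (averaged). Of 557 gene values 256 came past the threshold with it and 0 left, 1 moved without a call, and of 264 list tests 24 became calls, 7 ended and 13 moved without one. The 557 values are those of named genes, and the naming rule was also applied to the fit with the block. The 256 therefore do not measure how often the block changes a call among all genes. Under the block, an adjusted p under 0.1 gave 3748 (Myelin against PDL), 3633 (Laminin against PDL), 29 (Myelin against Laminin), 3639 (laminin plus myelin against PDL) and 2555 (averaged). A 2-fold change gave 487, 165, 437 and 110 for these without Myelin against Laminin. DESeq2 with the block gave 2414 for Laminin against PDL, 66 for laminin plus myelin against Laminin, 77 for Myelin against Laminin and 241 for the interaction.

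With the share of reads outside genes as a covariate, Myelin against PDL, laminin plus myelin against PDL and the averaged effect had 0 genes. With the block as well, the counts were 0 (Myelin against PDL), 0 (Laminin against PDL), 42 (laminin plus myelin against Laminin), 50 (Myelin against Laminin), 0 (laminin plus myelin against PDL) and 7 (averaged). That covariate reversed Vegfa (0.01 with an SE of 0.184) and Pfkp (0.221 with an SE of 0.326) in Myelin against PDL. It turned the direction of cytoskeleton_transport in Myelin vs PDL (adjusted p = 0.358), cytoskeleton_transport in Laminin_Myelin vs PDL (0.294), cytoskeleton_transport in Myelin averaged over laminin (0.709), pan_neuronal in Myelin averaged over laminin (0.0593) and iglon_family in Myelin averaged over laminin (0.393). Of the 76 list calls, 4 held with an estimated correlation, fry called 1, and with the covariate 128 lists were called.

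Leaving out 1 library at a time gave 2 to 425 genes for Myelin against PDL, 0 to 276 for laminin plus myelin against PDL, 0 to 3 for laminin plus myelin against Laminin, 1 to 4 for Myelin against Laminin and 4 to 673 for the averaged effect. Laminin against PDL, laminin plus myelin against Myelin and the interaction stayed at 0. With the block the ranges were 160 to 2422, 14 to 2271, 6 to 186, 9 to 336 and 96 to 4795, and 0 to 2481 for Laminin against PDL and 0 to 83 for the interaction.

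Lists whose direction turned without a library, with the lowest and highest adjusted p over the libraries left out, are given with the value at the turn where it was not the highest alone. Against Laminin, laminin plus myelin gave basement_membrane_ecm (1.25e-05 to 0.779, turned at 0.648 and 0.779), ribosomal_protein (8.92e-09 to 0.962, turned at 0.523 and 0.962), cholesterol_synthesis (0.000435 to 0.885), neural_progenitor (3.62e-05 to 0.474, turned at 0.204) and cell_cycle (1.42e-10 to 0.452, turned at 0.28). Myelin against Laminin gave basement_membrane_ecm (7.83e-06 to 0.776), ribosomal_protein (4.5e-08 to 0.602, turned at 0.108 and 0.602), neural_adhesion (3.05e-07 to 0.653), neural_progenitor (4.05e-06 to 0.88) and cell_cycle (1.76e-07 to 0.776, turned at 0.0865). Laminin plus myelin against Myelin gave cholesterol_synthesis (7.51e-12 to 0.76, turned at 0.632).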

Other observations

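The choice of the block for naming genes, the fit without Laminin replicate 1 and the tests of STAT3 signalling were made after the data had been seen, and so were the counts of regroupings that part the pairs without the block, while the other counts of regroupings were planned. In Myelin against PDL with the block, genes of several groups moved, and those named here passed only with it. Of 22 immediate early genes, which respond quickly to stimulation, 6 rose and 1 fell, among them Fos (0.82 ± 0.13, adjusted p = 0.00402; 33.8 ± 14.2 against 18.6 ± 5.90 CPM), Fosb (0.76 ± 0.15) and Nr4a1 (0.56 ± 0.11). Of 29 genes of spinal neuron classes, 3 rose and 2 fell. Slc18a3, the vesicular transporter of acetylcholine found in motor neurons, rose (1.04 ± 0.25, 0.02), while the glycine transporter Slc6a5 (-0.63 ± 0.15, 0.0165) and the GABA-synthesizing enzyme Gad2 (-0.26 ± 0.06, 0.0206) fell. Of the sensory and neural crest genes, the peripheral filament Prph rose (2.63 ± 0.16, 5.08e-06; 6.50 ± 3.43 against 1.06 ± 0.684 CPM). Of 12 oligodendrocyte precursor genes 4 rose and 1 fell, with Bcas1 at 1.77 ± 0.27, Cspg4 at 1.33 ± 0.32 and Gpr17 at -0.85 ± 0.22. Of 26 genes of sterol and lipid loading 3 rose and 1 fell (list adjusted p = 0.0119, and adjusted p = 0.266 with an estimated correlation; 0.0586 without the block), with the carrier Apoe at 1.22 ± 0.16 and the droplet protein Plin2 at 1.01 ± 0.17. The basement membrane collagen Col4a1 rose as well (0.94 ± 0.16). The guidance receptor Robo3 (-0.82 ± 0.17), the kinase Rock1 (-0.64 ± 0.10) and the phosphatase Ptprd (-0.53 ± 0.10) fell, in the comparison with PDL and its higher share of reads outside genes.

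Laminin replicate 1 had the lowest share of reads outside genes (8.46%). Without it, the fit with the block called 186 genes in laminin plus myelin against Laminin (104 higher, 82 lower), including all 16 called with it, and 336 in Myelin against Laminin (17 of 18 shared). The averaged effect had 4795 genes, including all 1358, and the interaction 83, of which 82 were positive. Laminin replicates 2 and 3 had 13.2% and 13.7% of reads outside genes, above every library with myelin (up to 12.4%). Without Laminin replicate 1, effects of myelin can therefore not be told apart from this share in the first 3 of these results. No fit without it took the share into account. Mobp (6.21 ± 0.34) and Prph (2.98 ± 0.17) were among the rises of the first comparison, and Col11a2, a fibrillar collagen (-0.88 ± 0.16, adjusted p = 0.0233), and Miat, a nuclear long noncoding RNA (-0.76 ± 0.15, 0.0458), among the falls. In the interaction H2-M5 (1.37 ± 0.25, 0.0335) was the largest positive value under the naming rule. Lyz2, the lysozyme of macrophages (-0.77 ± 0.11, 0.0158), was the single negative one. Ribosomal proteins were then higher, not lower, in laminin plus myelin against Laminin (2.98e-10, and adjusted p = 0.115 with an estimated correlation).

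Stat3, Prph and Spp1 were higher in wells with myelin (1.08 ± 0.09, 2.82 ± 0.11 and 2.30 ± 0.34, averaged over laminin with the block), and signalling by cytokines of the IL-6 family through STAT3 is a hypothesis for this. A list of 25 STAT3 targets, written after these genes were seen and without them, was tested: 23 could be measured, 16 were above 0 and 6 rose (camera p = 3.84e-05, and p = 0.164 with an estimated correlation). The members that rose were Serpina3n (3.05), A2m (2.11), Osmr (1.67), Irf1 (0.88), Socs3 (0.65) and Il6st (0.23), but the median was 0.18 with bounds of -0.05 and 0.34, so the hypothesis rests on part of the list. Without the block 0 of the 23 passed in this comparison (p = 1.99e-05, and p = 0.184 with an estimated correlation). With the block 0 passed in laminin plus myelin against Laminin (7.56e-05, and p = 0.178 with an estimated correlation) and 0 in Myelin against Laminin (1.41e-05, and p = 0.148 with an estimated correlation). RNA carried in with the coat was neither excluded nor shown as a source. Over the 3 genes and the 5 risen targets with an excess in every well, 8 in all, the spread around Mobp was a median 1.77 times that around the same culture without myelin. The SDs were 0.68 and 0.14 for Prph, 0.55 and 0.29 for Stat3, and 1.53 and 1.06 for Spp1.

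Other regroupings of the libraries were counted for each result. For pairs of coats the splits are too few for a share under 0.05. For Myelin against PDL, 1 of 10 splits, the real one, gave as many genes (360, highest other 0), and with the block 1 of 4 (2268, highest other 0). The same held for laminin plus myelin against PDL (196 and 0; with the block 2133 and 0), laminin plus myelin against Laminin (3 and 0; with the block 16 and 4) and Myelin against Laminin (4 and 0; with the block 18 and 0). For Laminin against PDL all 10 splits gave 0 as the real one did, and with the block 1 of 4 gave as many (1282, highest other 0). For laminin plus myelin against Myelin, 10 of 10 and with the block 4 of 4 splits gave 0, the real value.

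For the averaged effect, the splits that part the pairs as the real one does were counted after the drawn ones had been seen. In the fit without the block, 2 of these 32 called as many genes as the real one (4, highest other 673), and with the block 2 of 32 did (1358, highest other 3574), so chance cannot be excluded for either count. The other split was the same in both fits. It exchanged Laminin replicate 1 with replicate 1 of laminin plus myelin and called several times the real count, which points to a structure of the samples in which Laminin replicate 1 stands apart. For the lists without the block, 1 of the 32, the real one, gave as many calls (21, highest other 20). This tally was added after the planned draw below had been seen, and the real split leads by 1 call. The averaged effect had 19 list calls with relative log expression factors and 18 with upper-quartile factors. Chance is therefore not excluded for the lists. The 100 drawn splits differ in that most leave libraries of the same number together. Of these, 3 gave as many genes (4, highest other 3044) and 26 as many lists (21, highest other 24). The split with 3044 put all 4 replicates 1 on one side and all 4 replicates 3 on the other, a structure by replicate number. For the interaction, the real count of 0 is met by any split, 100 of 100 without the block (highest other 3128) and 32 of 32 with it (highest other 3574), so these tallies decide nothing.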
